A study of Mus musculus with 4 samples.

How the data were processed

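RNA of mouse peritoneal macrophages, immune cells taken from the lining cavity of the abdomen, was sequenced after 24 h with LUP at 0.5 mg/ml or with complete medium as the vehicle. The abbreviation LUP is not spelled out in the labels and is used here as given. There were 2 libraries per group, numbered 1 and 2 in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I, checked for integrity and made into paired-end Illumina libraries with a TruSeq RNA kit. Whether the kit kept the strand is not stated there, so reads of a gene and of an overlapping or antisense gene cannot be told apart.

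One table of the whole series was used. It lists 55414 Ensembl genes with their symbols. The expected counts per gene and library are the authors' estimates, deposited without scaling between libraries, and per the submitters' processing notes fastp, HISAT2, StringTie and RSEM were named, with no version or role. The TPM values per library, and the mean TPM of each group, were also computed and deposited by the authors. The fold (a ratio), its log2 and the p-value and adjusted p-value of the comparison were deposited by the authors as well, and the test behind them is not given in the sources used here. The genome build and annotation are likewise not given there, so no coordinates are printed. Expected counts need not be whole, because reads that fit several genes are shared out between them. Genes said below to have whole counts were whole in all 4 libraries (within 0.001 of a whole number). Taken 1 library at a time, between 53.55% and 54.98% of the reads lay in genes whose counts were whole in that library. Values of genes with close copies, such as the Ifit, Fpr, Gbp, Ly6 and class I histocompatibility families, are therefore uncertain in how they are split between copies.

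Expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, edgeR's default filter on low counts and treatment as the only term. Benjamini-Hochberg adjustment was made over the 13355 genes tested, and a gene was called at an adjusted p under 0.05. The labels name TPM columns and the table gives counts beside them, so the count test fixed beforehand for that case was used. All fold changes are LUP over vehicle. Levels are given as the authors' TPM, mean ± SD over the 2 libraries of a group, and folds come from the fitted counts, so a fold can differ a little from the ratio of the TPM means. For 44 gene lists written before the data were examined (responses, markers of other cell types and signs of RNA quality; 1005 symbols, of which 8 were not matched in the table), members called in each direction were counted, and each list was compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment was made over the lists. Some genes stand in several lists, such as Sod2 (NF-kB and oxidative stress) and Clec4e (classical activation and pattern recognition), so the calls of lists are not independent. A version of camera that estimates the correlation from the data, which has only the 2 residual degrees of freedom of 4 libraries, was run beside it. With so few it can hardly call any list, so its adjusted p-values do not tell whether correlation between genes undid a call. Biological process and KEGG terms that the table pairs with its genes, with 10 to 500 tested members, were compared by one-sided Fisher's exact tests against the tested genes that carry such an annotation.

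Genes are named by a rule fixed beforehand. It takes the 12 largest rises and 12 largest falls among called genes with at least 10 TPM in the higher group, no overlap between the groups' TPM and a symbol that is not a predicted-gene or clone name. It adds from each list up to 4 called members with the highest mean level and, where fewer than 2 are called, up to 2 others. Genes named outside this rule are said to have been chosen after their values were seen. A fold against a group with no reads is a lower bound against a floor of 3 counts per library. Where a group held 1 to 3 reads in total the ratio of counts is given with its exact 95% interval, which covers counting error only.

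The libraries held 19949818 to 23617618 counts. On counts simulated from these libraries' means and sizes, with 13284 genes tested, the test made 8 false calls. It recovered 84% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Camera called the changed list, of 20 genes with mixed rises, and 1 of 50 unchanged lists. Simulated genes varied independently with the same dispersion, and only 50 well-covered genes changed at each fold. These rates therefore do not carry over to lists whose genes vary together, such as the ribosomal protein list (estimated correlation 0.66). The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, no exact permutation of the labels could reach a p under 0.05.

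Alternatives fixed beforehand were limma with trend on log2(TPM + 1) and with pseudocounts of 0.1 and 5, no filter on low counts, a filter of at least 5 TPM in 2 libraries, DESeq2 size factors, quantile normalization, DESeq2 1.42.0 in place of edgeR, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a fold of at least 2, camera with an estimated correlation, fry, and all tested genes as the background of the term tests. A test against a 1.5-fold change and a fit on genes with whole counts only were added after the data had been seen. For a check of length and GC content, lengths were the deposited ones and GC content came from the longest transcript per gene in GENCODE M21, matched by Ensembl identifier for 99.8% of tested genes. Figures were drawn with matplotlib 3.10.9.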

Results

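Gene expression was measured by RNA sequencing in mouse peritoneal macrophages kept for 24 h with LUP at 0.5 mg/ml or with vehicle, with 2 libraries in each group. The LUP libraries held 23617618 and 22460913 counts and the vehicle libraries 19949818 and 23172691. Of the 55414 genes listed, 22540 had at least 1 read in a library and 13355 were tested. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 2.746 between the vehicle libraries and 3.654 between the LUP libraries (1.902 and 2.833 over genes with whole counts). They were therefore not taken for 1 library deposited again and were counted as 2 each, as labelled. This does not tell separate cultures from technical repeats. The 10 most abundant genes of a library took 15.38% and 15.89% of the counts with LUP and 19.95% and 19.46% with vehicle.

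The comparison of LUP with vehicle asks how the macrophage transcriptome differed after exposure. With LUP, all 34 measured genes of the type I interferon list, 17 of 19 chemokine genes and 11 of 15 inflammatory cytokine genes were higher. Ccl5, a chemokine that attracts T cells and monocytes, stood at 1816 ± 111 TPM with LUP and 12.6 ± 1.01 TPM with vehicle (n = 2 each), a 154-fold rise. In the oxidative stress list 30 of 31 genes were higher, and in the lysosome and autophagy list 25 of 38 were lower and 8 higher. Camera called 19 of the 44 lists, and none of them with an estimated correlation (lowest adjusted p = 0.482 with an estimated correlation). Apoe, the gene of the lipid carrier apolipoprotein E, fell from 30376 ± 615 to 10813 ± 354 TPM. By edgeR's quasi-likelihood test 6785 of the 13355 tested genes (50.8%) were called at an adjusted p under 0.05, 3621 higher and 3164 lower with LUP. Of these, 1512 changed at least 2-fold, 851 upward and 661 downward.

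The share of calls that were higher was 53.37% with TMM scaling, 53.97% with DESeq2 size factors and 41.36% after quantile normalization. It was 43.49% with limma on log2(TPM + 1), which also differs in the measure, the test and the 12059 genes tested. The median change of all genes shifted by -0.09 after quantile normalization and by -0.10 with limma on log2(TPM + 1), so smaller log2 changes are not told apart from a shift of all genes.

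**Figure D1:**
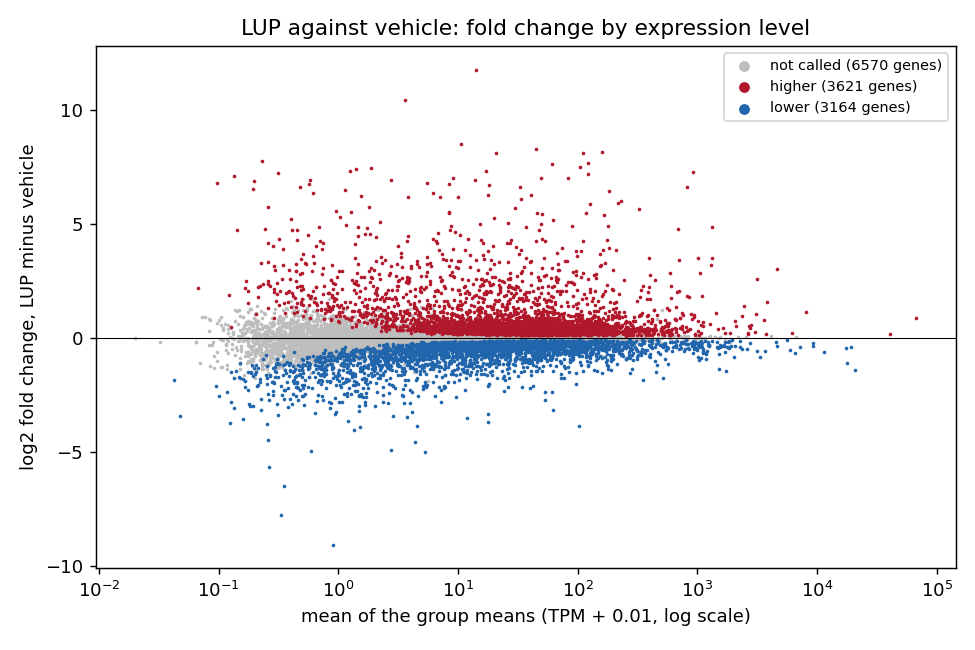
Log2 fold change (LUP minus vehicle) of each of the 13355 tested genes against its mean level in TPM on a log axis; red points are the 3621 genes called higher, blue points the 3164 called lower and grey points the genes not called. Fpr3 lies at 8.26 and Mamdc2 at -3.85.

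The largest rises included Fpr1, Fpr2 and Fpr3, genes of the formyl peptide receptor family, whose members sense bacterial peptides. Fpr2 rose 284-fold, from 1.24 ± 0.502 to 318 ± 24.6 TPM, Fpr1 129.6-fold, from 1.35 ± 0.0495 to 164 ± 15.8 TPM, and Fpr3 from 0.31 ± 0.0849 to 89.7 ± 1.69 TPM. The neutrophil-attracting chemokine Cxcl3 rose from 1.23 ± 0.46 to 243 ± 22 TPM, a log2 change of 7.65 (SE 0.123, adjusted p = 1.25e-19). Ly6i, a Ly6 family surface protein gene, reached 222 ± 17.5 TPM from 0.725 ± 0.587 TPM, and the membrane protein gene Ms4a4c 120.5 ± 30.3 TPM from 0.83 ± 0.481 TPM. H2-M2, a nonclassical class I gene, rose 144-fold to 243 ± 12.9 TPM. The interferon-induced genes Ifit3 and Gbp6 rose 180.0-fold and 157-fold. The size of the Gbp6 rise is uncertain, with 14 and 3 counts in the vehicle libraries. Its log2 change was 7.30 in the main test and ran from 2.87 to 8.87 over all settings, some of which add pseudocounts that shrink changes from a low level. Fpr3, Ly6i, Ms4a4c and Il1b had 9, 11, 11 and 5 reads in the vehicle libraries together. The sizes of those rises are therefore uncertain as well. Ifit3b had 3 reads in the vehicle libraries together and 1215 with LUP, a ratio of 379 after scaling to library size, with an exact 95% interval of 129 to 1840. The pseudogene Eif4a-ps4, whose reads are shared with related genes and whose level is therefore uncertain, had no reads with vehicle after rounding and 48.19 and 8.16 TPM in the LUP libraries. It was at least 136-fold higher on the mean of both and at least 40.1-fold from LUP replicate 2 alone.

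Among the largest falls, Mamdc2, a proteoglycan gene, dropped 14.4-fold from 194 ± 7.4 to 12.4 ± 0.255 TPM. Scgb1a1, a secretoglobin gene, dropped 13.1-fold and Cdo1, the cysteine dioxygenase that begins cysteine breakdown, 11.4-fold. Ctse, the aspartic protease cathepsin E, went from 32.5 ± 0.608 to 3.04 ± 0.594 TPM, Bex1 from 112 ± 3.09 to 11.5 ± 2.39 TPM and Cmbl from 12.7 ± 1.65 to 1.62 ± 0.728 TPM. Lsp1, an actin-binding leukocyte protein gene, dropped 6.68-fold and Cdkn1c, an inhibitor of cyclin-dependent kinases, 5.24-fold. Fam83f, Tnni2, Pianp and Tcp11l2 dropped 6.05-fold, 5.79-fold, 5.14-fold and 4.87-fold.

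**Figure D2:**
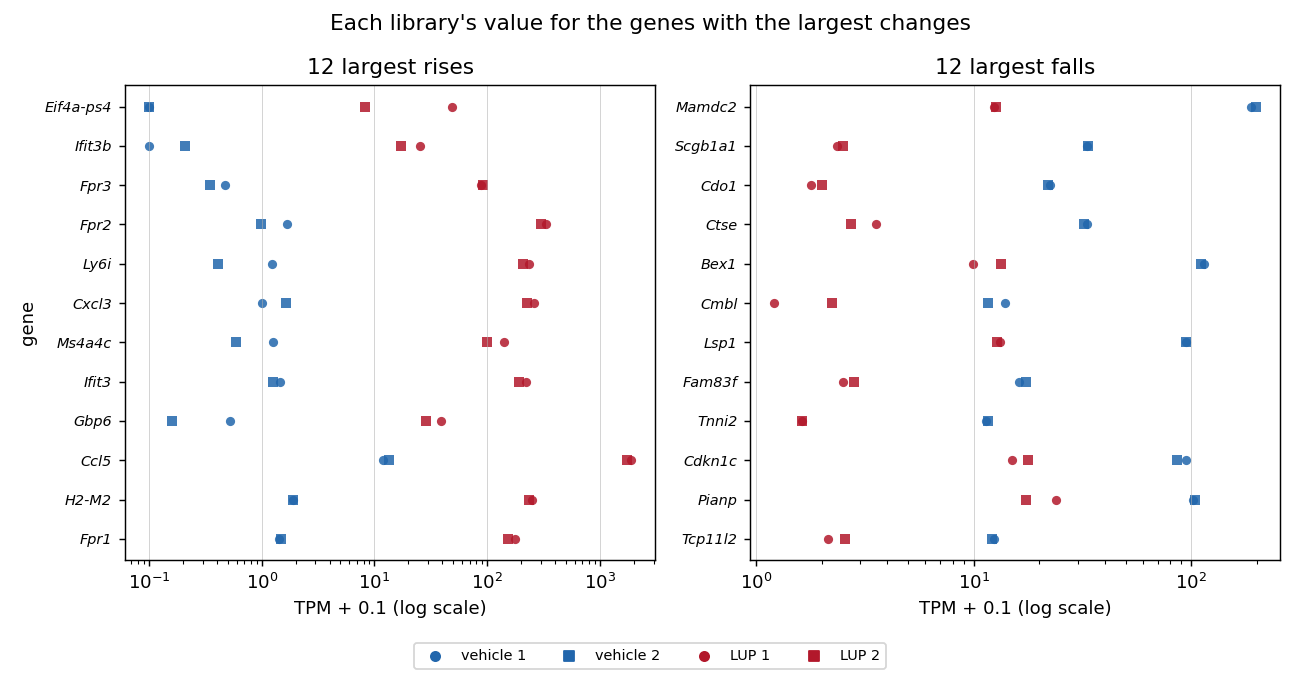
TPM plus 0.1 on a log axis in each of the 4 libraries (blue, vehicle; red, LUP; circles, replicate 1; squares, replicate 2) for the 12 largest rises and the 12 largest falls. In each of the 24 genes both LUP libraries lie on the same side of both vehicle libraries, which the rule that picked them required. Eif4a-ps4 shows the widest gap between LUP libraries on this axis, at 48.19 and 8.16 TPM.

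Interferon-stimulated genes moved together. All 34 measured members of the type I interferon list rose, by a median log2 change of 3.83 (camera adjusted p = 1.95e-20; adjusted p = 0.534 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose 60.3-fold to 428 ± 22 TPM, Irf7, a transcription factor of the interferon response, 49.8-fold, Oasl2 19.5-fold and the tetherin gene Bst2 10.6-fold. Of 22 genes of the interferon gamma list 20 rose and 1 fell (median 2.29, adjusted p = 1.87e-10; adjusted p = 0.482 with an estimated correlation), among them the immunoproteasome subunit Psmb8 (4.25-fold) and Cd274, which encodes the checkpoint ligand PD-L1 (3.38-fold). All 18 members of the class I presentation list rose (median 1.57, adjusted p = 1.85e-10; adjusted p = 0.482 with an estimated correlation). B2m, the shared light chain, went from 5304 ± 36.9 to 10868 ± 505 TPM and H2-K1 from 2019.5 ± 7.32 to 5599 ± 5.94 TPM. The counts of these 3 lists adjusted over the list alone were 34, 20 and 18 higher, and 0, 1 and 0 lower.

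The interferon genes themselves were near the floor. Of the 18 type I interferon genes listed, only Ifnz had more than 3 counts in a library, with 3 and 4 counts with vehicle. Ifnb1 had none in any library, which allows up to 3 counts in each. Ifng, the gene of interferon gamma, had 10 counts in each LUP library and 0 in each vehicle library and was below the filter. The T and NK cell marker list was not called (0 higher and 2 lower of 5, downward, adjusted p = 0.58; adjusted p = 0.861 with an estimated correlation), and without a filter on low counts it was called higher (adjusted p = 0.00392). The 2 lower members of the list, Il7r and Cd28, fell 2.23-fold and 9.54-fold. Il7r had 27547 reads in all with vehicle and 12897 with LUP, and Cd28 had 908 and 99. Members below the filter had few reads. Cd3g, a subunit of the T cell receptor complex, had 13 and 8 counts with LUP and 2 and 1 with vehicle. The costimulatory receptor gene Icos had 11 and 8 counts with LUP and 0 and 1 with vehicle. Of the 23 T and NK cell markers below the filter, 21 had more reads with LUP, 1 fewer (Zap70) and 1 the same number (Cd4), 151 reads in all with LUP and 50 with vehicle. Among all 9185 genes below the filter with a read, 3982 (43.4%) had more reads with LUP. This tally was made after the values were seen and has no test. Ifnz, Ifnb1, Ifng, Cd3g, Icos, Zap70 and Cd4 were chosen after their values were seen.

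Inflammatory mediators rose with them, as did the neutrophil marker list (adjusted p = 0.0122; adjusted p = 0.534 with an estimated correlation). In the classical activation list 29 of 32 genes were higher and 2 lower (median 2.05, adjusted p = 2.68e-12; adjusted p = 0.482 with an estimated correlation). The acute-phase gene Saa3 went from 1099 ± 19.2 to 8199.9 ± 300.3 TPM and the protease inhibitor gene Slpi from 89.2 ± 2.99 to 2561 ± 41.9 TPM. Of 15 cytokine genes 11 rose and none fell (median 2.55, adjusted p = 7.4e-06; adjusted p = 0.534 with an estimated correlation), with Tnf at 7.67 ± 1.1 and 74.2 ± 7.91 TPM and Il1b at 0.155 ± 0.0354 and 16.7 ± 1.58 TPM with vehicle and LUP. Chemokines rose in 17 of 19 cases and fell in 1 (median 2.60, or 2.35 with the member lacking vehicle reads at its bound; adjusted p = 1.13e-07; adjusted p = 0.482 with an estimated correlation), among them Cxcl16 (3.54-fold) and the platelet factor gene Pf4 (4.74-fold). In the NF-kB list 21 of 24 genes rose and 2 fell (median 1.42, adjusted p = 1.21e-08; adjusted p = 0.482 with an estimated correlation). The inhibitor gene Nfkbia rose 3.81-fold and the mitochondrial superoxide dismutase gene Sod2 11.3-fold. Pattern recognition receptors rose in 17 of 28 cases and fell in 7 (median 0.47, adjusted p = 0.00456; adjusted p = 0.621 with an estimated correlation), led by Clec4e, the receptor Mincle (27.4-fold). Eicosanoid genes rose in 13 of 22 cases and fell in 5 (adjusted p = 0.0395; adjusted p = 0.534 with an estimated correlation). That call was lost without LUP replicate 1 (0.066), without LUP replicate 2 (0.0704) and with a filter of at least 5 TPM (0.0561), in a range of 0.00873 to 0.0704 over the alternatives that kept the preset correlation. Adjusted over the list alone, these 6 lists had 29, 11, 17, 21, 17 and 14 higher genes and 2, 0, 1, 2, 7 and 5 lower genes, in the order given.

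**Figure D3:**
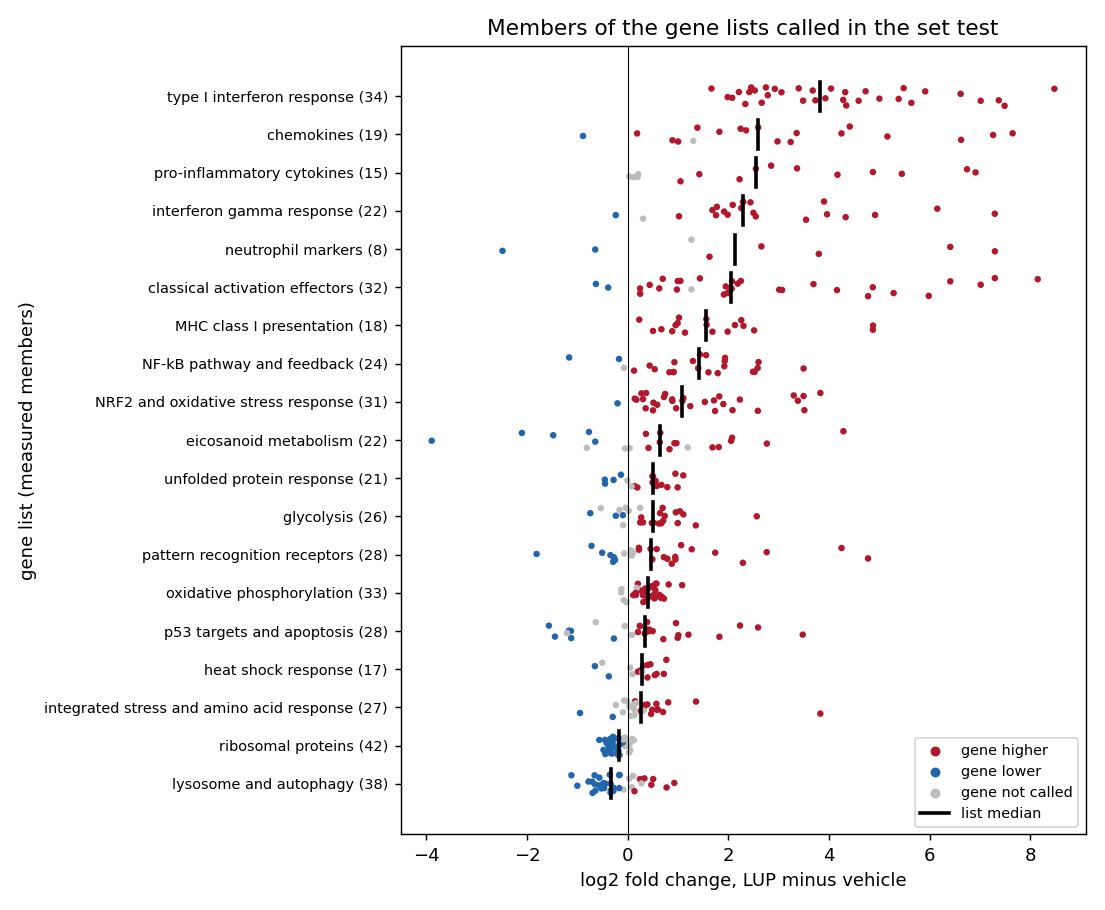
Log2 fold change (LUP minus vehicle) of each measured member of the 19 lists called by camera; each point is a gene (red, higher; blue, lower; grey, not called) and each black bar the list's median. Medians run from 3.83 in the type I interferon list to -0.34 in the lysosome list, and 17 of the 19 lists moved upward. A gene that stands in several lists is drawn in each of them.

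The oxidative stress list rose in 30 of 31 genes and fell in 1 (median 1.09, adjusted p = 2.4e-12; adjusted p = 0.534 with an estimated correlation). The peroxiredoxin gene Prdx1 went from 986 ± 9.53 to 5360.1 ± 502 TPM, the heme oxygenase gene Hmox1 from 512 ± 3.78 to 1687 ± 70.9 TPM and the ferritin heavy chain gene Fth1 from 49499 ± 951 to 85380.2 ± 3319 TPM. Glycolytic genes rose in 17 of 26 cases and fell in 3 (median 0.50, adjusted p = 0.00085; adjusted p = 0.534 with an estimated correlation), with Pkm, a pyruvate kinase, up 2.15-fold and Gapdh up 2.05-fold. Nuclear genes of the respiratory chain rose in 28 of 33 cases and none fell (median 0.40, adjusted p = 1.04e-05; adjusted p = 0.621 with an estimated correlation), among them the ATP synthase gene Atp5b (1.6-fold). The unfolded protein list rose in 15 of 21 genes and fell in 4 (adjusted p = 0.00456; adjusted p = 0.534 with an estimated correlation), with the chaperone gene Hspa5 up 1.47-fold. The integrated stress list rose in 14 of 27 genes and fell in 2 (adjusted p = 0.00618; adjusted p = 0.534 with an estimated correlation), while the stress-induced factor gene Atf3 fell 1.93-fold. Heat shock genes rose in 11 of 17 cases and p53 and apoptosis genes in 18 of 28 (adjusted p = 0.0349 and 0.0395; adjusted p = 0.621 and 0.534 with an estimated correlation); 2 and 6 members fell. Both calls were lost with a replicate block (0.0538 each) and without LUP replicate 1 (0.0768 and 0.0616), the heat shock call also without vehicle replicate 1 (0.0548), with limma on log2(TPM + 1) (0.124) and with the filter of at least 5 TPM (0.0963), and the p53 call without LUP replicate 2 (0.081). Over the alternatives that kept the preset correlation the values ran from 0.0103 to 0.13 and from 0.0103 to 0.081. Adjusted over the list alone, 30, 17, 29, 15, 14, 11 and 18 genes of these 7 lists were higher and 1, 3, 1, 4, 3, 2 and 6 lower.

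Lysosome and autophagy genes fell in 25 of 38 cases and rose in 8 (median -0.34, adjusted p = 0.00526; adjusted p = 0.621 with an estimated correlation; 25 lower and 10 higher adjusted over the list alone). The lysosomal proteases Ctsd and Ctsb went from 24927 ± 219 to 10715 ± 181 TPM and from 8346 ± 35 to 4757 ± 160.1 TPM, and Gpnmb, a membrane glycoprotein gene, from 14122 ± 21.5 to 8578 ± 229.6 TPM. Ribosomal protein genes fell in 29 of 42 cases and none rose (median -0.18, adjusted p = 0.00051; adjusted p = 0.723 with an estimated correlation; 29 lower and 1 higher adjusted over the list alone), with Rps15 down 1.36-fold. Transcripts of the mitochondrial genome, a sign of RNA quality as well, were lower in 9 of 13 cases and higher in 1, with the same counts adjusted over the list alone, and their list missed the threshold (adjusted p = 0.0749, with 0.0216 to 0.116 over the alternatives that kept the preset correlation; adjusted p = 0.621 with an estimated correlation); mt-Cytb fell 1.31-fold. Mitochondrial transcripts took 1.104% and 1.046% of the counts with LUP and 1.143% and 1.14% with vehicle.

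Single genes of lipid handling fell without their lists being called. The fatty acid binding protein gene Fabp4 dropped from 795 ± 0.827 to 233 ± 3.21 TPM, the lipid droplet coat gene Plin2 1.8-fold and Pparg, a nuclear receptor of lipid metabolism, from 64.8 ± 0.17 to 25.3 ± 0.346 TPM. Fatty acid oxidation genes were higher in 2 and lower in 8 of 20 cases (adjusted p = 0.0815, with 0.0172 to 0.27 over the alternatives that kept the preset correlation; adjusted p = 0.621 with an estimated correlation), fatty acid synthesis genes in 9 and 9 of 26 (0.997), cholesterol synthesis genes in 6 and 9 of 24 (0.342) and cholesterol efflux genes in 7 and 4 of 17 (0.58). The alternative activation list held 3 higher and 9 lower genes of 16 (adjusted p = 0.342), with a median log2 change of -0.38 and a mean of 0.31. Complement genes split, with Cfb, complement factor B, up 97.9-fold and C1qb and C1qc, subunits of the first component, down 1.67-fold and 1.69-fold (8 higher and 8 lower of 18, adjusted p = 0.997, median -0.29, mean 0.67 and an upward camera direction). Class II presentation genes (5 higher and 5 lower of 12, adjusted p = 0.946), phagocytic receptors (10 and 11 of 27, 0.946) and immediate early genes (6 and 10 of 25, 0.662) were not called either. The same held for hypoxia genes (8 and 8 of 22, 0.858), cell cycle genes (3 and 11 of 40, 0.0813, and 0.0145 without vehicle replicate 1), matrix remodelling genes (18 and 10 of 34, 0.103), metal handling genes (10 and 4 of 16, 0.137) and anti-inflammatory mediators (6 and 3 of 11, 0.159). For phagocytic receptors the median (0.06) and mean (0.24) were above 0 and the camera direction was downward, and for hypoxia genes the median was -0.06 and the mean 0.09. Matrix remodelling genes were called upward without a filter on low counts (0.0129) and after quantile normalization (0.0463), and metal handling genes upward after quantile normalization (0.0355). Anti-inflammatory mediators were called upward without that filter (0.025) and alternative activation genes downward with a filter of at least 5 TPM (0.0402). With an estimated correlation none of these 4 lists was called by camera, and neither was the cell cycle list. The adjusted p was 0.534 for the first 3 and for the cell cycle list, and 0.621 for alternative activation. Adjusted over the list alone, 5 cholesterol efflux and 9 cell cycle genes were lower and 5 alternative activation genes were higher, and the other counts of this paragraph were the same.

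Macrophage lineage genes went both ways, 9 higher and 14 lower of 26 (adjusted p = 0.578, median -0.24, mean 0.08). Lyz2, the lysozyme gene, was 1.31-fold lower, a direction that quantile normalization turned to a log2 change of 0.128. Large peritoneal macrophage genes were higher in 9 and lower in 9 of 23 cases (adjusted p = 0.858, median -0.32, mean 0.66), and monocyte and small peritoneal macrophage genes in 5 and 10 of 18 (0.192, median -0.54, mean 0.75). Housekeeping genes were higher in 8 and lower in 3 of 15 cases (adjusted p = 0.267); the actin gene Actb was 1.13-fold higher, which quantile normalization turned to a log2 change of -0.117, and Eef1a1, a translation elongation factor gene, fell 1.45-fold. Adjusted over the list alone, 10 large peritoneal macrophage genes were higher, and the other counts here and among the cell type markers were the same.

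Markers of other cell types were measured beside these groups. The neutrophil list was called higher, with 5 higher and 2 lower of 8 measured genes (median 2.14, adjusted p = 0.0122; adjusted p = 0.534 with an estimated correlation; 5 and 2 adjusted over the list alone). The siderophore-binding protein gene Lcn2 went from 4.61 ± 0.255 to 363 ± 13.5 TPM and the collagenase gene Mmp8 from 15.2 ± 0.969 to 197 ± 23.8 TPM, while Csf3r, the receptor of granulocyte colony-stimulating factor, fell 1.56-fold. Mesothelial and fibroblast markers were higher in 3 and lower in 9 of 19 cases (adjusted p = 0.134, and 0.016 without LUP replicate 1), with Lrrn4 at 2.94 ± 0.53 and 0.72 ± 0.24 TPM and the collagen gene Col1a1 at 37.8 ± 2.21 and 48.4 ± 7.58 TPM with vehicle and LUP; limma on log2(TPM + 1) did not call Col1a1 (adjusted p = 0.085). Markers of dendritic cells (3 higher and 2 lower of 10, adjusted p = 0.178), B cells (1 and 2 of 6, 0.578) and T and NK cells (0 and 2 of 5, 0.58, median 0.17, mean -0.59 and a downward camera direction) were not called. Nor were mast cell, basophil and eosinophil markers (1 and 1 of 6, 0.886) or endothelial, erythroid and platelet markers (2 and 3 of 6, 0.938) called. Without a filter on low counts the T and NK cell list turned upward and was called (adjusted p = 0.00392). Limma on log2(TPM + 1) called the dendritic cell list upward (0.0359). With an estimated correlation and the filter, adjusted p = 0.861 for the T and NK cell list and adjusted p = 0.534 for the dendritic cell list. For the mesothelial and fibroblast list it was 0.792.

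Of 1896 terms tested in each direction, 144 were enriched among genes higher with LUP and 8 among genes lower. Fisher's tests treat genes as independent, so p-values can be too small where members vary together, as ribosomal protein genes did (estimated correlation 0.66). The terms named here and below were picked without a rule fixed beforehand. The smallest p among higher genes was that of Parkinson disease (139 of 213, Fisher's exact test, adjusted p = 2.65e-18). The KEGG proteasome term held 40 higher genes of 43 where 14.58 were expected by chance (Fisher's exact test, adjusted p = 2.15e-13), and the cellular response to interferon-beta 35 of 42 where 12.29 were expected (adjusted p = 9.24e-11). Defense response to virus held 79 of 126 (adjusted p = 2.04e-12). Among lower genes, the KEGG lysosome term held 61 of 117 where 29.69 were expected (adjusted p = 6.31e-07) and the ribosome term 58 of 127 where 32.22 were expected (adjusted p = 0.000395).

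In the authors' deposited table, 1254 genes had an adjusted p under 0.05 with at least a 2-fold difference. The table's fold is vehicle over LUP, since the 489 genes it labels up have a lower mean TPM with LUP and the 765 it labels down a higher one. Of these genes of the authors' deposited table, 1227 were tested here and all were called in the direction of their TPM.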

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

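The test against a 1.5-fold change and the fit on genes with whole counts were chosen after the results were seen; the other alternatives were fixed before. Against 6785 genes called (3621 higher, 3164 lower) and 1512 at 2-fold or more (851 and 661, the counts when that fold is required), limma on log2(TPM + 1) called 4449 genes (1935 higher, 2514 lower), of which 610 were higher and 424 lower at 2-fold or more; a pseudocount of 0.1 called 4414 (1920 higher, 2494 lower); a pseudocount of 5 gave 4460 (1937 higher, 2523 lower), and 590 at 2-fold or more (415 higher, 175 lower). The filter of at least 5 TPM left 835 at 2-fold or more (540 higher, 295 lower), with fewer genes tested. The test against a 1.5-fold change called 1698 (1004 higher, 694 lower). Among genes with whole counts 4016 were called (2099 higher, 1917 lower) and 933 at 2-fold or more (483 higher), with fewer genes tested. DESeq2 called 5085 genes. Leaving out each library in turn called 5607 to 6390 genes, of which 5445 to 6033 were called in the same direction with all libraries; the lone library left in a group is assumed to vary like the other group. Between 4 and 6 genes were called in the opposite direction with TPM values or quantile normalization, and 0 under the other settings. The cause was not tested where no smaller number of genes is named. Libraries that share a number did not deviate together (correlation across genes -0.066). With 2 libraries per group this shows no sign of a shared effect. It cannot tell whether equal numbers share an animal or a day, which the labels do not say. A replicate block called 6606 genes (3533 higher, 3073 lower) and 17 lists.

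With an estimated correlation 0 of the 19 lists were called by camera, and fry, which does not compare a list with other genes, called 34 lists. Over the settings that kept the preset correlation, 3 called lists lost their call in some setting, and 10 others were called in some setting. Directions turned for T and NK cell markers without a filter on low counts (upward, adjusted p = 0.00392), and with fry for fatty acid synthesis (downward, 0.0263) and macrophage lineage genes (upward, 0.0184). Quantile normalization turned Lyz2 to a log2 change of 0.13 and Actb to -0.12. With all tested genes as background, 211 terms were enriched among higher and 11 among lower genes. Depth limits genes near the floor of 3 counts per library.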

Other observations

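The tests of the proteasome genes, of mitochondrial transcripts with whole counts, of mesothelial and fibroblast markers and of neutrophil genes were chosen after the results were seen. Proteasome genes rose broadly with LUP. Psme2, a subunit of the proteasome activator PA28, rose from 125 ± 2.24 to 768 ± 11 TPM, and the constitutive catalytic subunit gene Psmb5 from 229 ± 4.19 to 456 ± 14.8 TPM. The assembly factor gene Pomp rose by a log2 change of 0.96 (SE 0.0516), and Psmd8 was lower (-0.20, SE 0.0361, adjusted p = 0.000161). Psme2, Psmb5, Pomp and Psmd8 were chosen after their values were seen. Genes of ribosome biogenesis were enriched among higher genes (40 of 70 where 23.73 were expected, Fisher's exact test, adjusted p = 0.00145), and genes of glycosaminoglycan degradation among lower genes (12 of 16 where 4.06 were expected, adjusted p = 0.0206).

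Mfge8, whose product bridges apoptotic cells to phagocytes, went from 2212 ± 19 to 788 ± 33.5 TPM and the tetraspanin gene Cd9 from 1395 ± 5.15 to 833 ± 0.728 TPM. Siglecf, a sialic acid-binding lectin gene known from eosinophils, went from 6.1 ± 0.707 to 0.945 ± 0.0636 TPM, and Vwf, the von Willebrand factor gene known from endothelium and platelets, from 93.4 ± 5.15 to 31.3 ± 1.65 TPM (n = 2 each, all 4 called lower by edgeR's quasi-likelihood test).

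A hypothesis is that the proteasome rise may reach beyond the subunits that interferon induces. Without the members of the interferon and class I lists, the median log2 change was 0.647 over 38 genes (35 higher and 1 lower), above the -0.06 to 0.27 that covered 95% of 10000 random lists matched on expression. Over all 43 genes it was 0.71. Because the term was picked for its many higher genes in these same data, the comparison with random lists adds no independent support. The 35 higher genes of 38 do show that the rise was not confined to members of the interferon and class I lists. They say nothing of its cause, nor of whether interferon also induces them.

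Nuclear genes of the respiratory chain rose while most transcripts of the mitochondrial genome were lower. The tables argue against gene length and GC content as the whole cause of the rise. After their trend, which held 1.5% of the variance, was removed, the median was 0.327 (0.399 before). It lay above the -0.138 to 0.241 of random matched lists. Those lists hold genes drawn at random, while genes of the respiratory chain list varied together (estimated correlation 0.709). That range is therefore too narrow for a strict test. Reads split with nuclear copies in the annotation are argued against for the fall. The 7 mitochondrial transcripts with whole counts had a median of -0.268 (largest SE 0.0594), with 6 lower and 0 higher. Nuclear copies outside the annotation would leave counts whole, so this test cannot speak to them. A response to LUP and a difference in how RNA of the mitochondria was captured stay open, and neither was tested.

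Of 10 mesothelial markers 8 were called lower with LUP (median log2 change -2.07), and fibroblast markers went both ways (median 0.31). The medians differed by -2.37 over 18 of the list's 19 measured genes (two-sided exact permutation p = 0.0024 across genes, which are not independent replicates). Split and test were chosen after the values were seen, so that p adds no independent support. A difference of medians also cannot exclude falls of both cell types by different factors. Among fibroblast markers Col1a1, Dcn and Pdgfrb were called higher and Pdgfra lower, so no common fall was seen in that part. A smaller share of mesothelial cells stays open: the 10 mesothelial markers differed among themselves (Cochran's Q p = 2.62e-05, from its chi-square approximation and not an exact test), but the 9 without Wt1, which the large peritoneal macrophage list also holds, did not pass (p = 0.144). The most abundant of them with vehicle, Lrrn4, stood at 2.94 ± 0.53 TPM. A response to LUP in those cells was not tested.

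The neutrophil marker list was called higher by camera (5 higher and 2 lower of 8, adjusted p = 0.0122; adjusted p = 0.534 with an estimated correlation), and neutrophils in the LUP cultures are a candidate source of the members that rose. The 9 strongly expressed neutrophil genes Ly6g, S100a9, Retnlg, Stfa2l1, Mrgpra2b, Ngp, Ltf, Mpo and Elane held 8 reads with LUP and 10 with vehicle, 0.104% of the rise of 7676 reads in Lcn2, though the 0 of S100a9 in every library may be a gap in the estimates, since S100a8 had reads. That set leaves out S100a8, which was called higher (635 reads against 197), and with it the share was 8.38%, so the test does not decide. Both shares count all reads with LUP, although S100a8 had 197 reads with vehicle too. Of the 14 list genes in no other list, 3 were tested, with S100a8 higher and Csf3r and Cxcr2 lower. The 9 genes together had no more reads with LUP than with vehicle, while S100a8 rose. Neutrophils and expression by the macrophages themselves were therefore not told apart here.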
